A study of Homo sapiens with 8 samples.

How the data were processed

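Total RNA was sequenced from the triple-negative breast cancer lines MDA-MB-231 and SUM159 after 24 hours at 20% or 1% oxygen, with 2 libraries for each of 4 groups. Libraries were made with a stranded total RNA kit, per the labels' protocols. The labels name FastQC, TopHat, Picard, featureCounts and edgeR and the hg19 genome, and do not say in which order or with which settings each was used. Which strand was counted is not given in the sources used here. Total RNA preparation keeps transcripts without a poly(A) tail, and the mitochondrial ribosomal RNAs stayed in the libraries and took a larger share of the SUM159 reads.

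The deposited signal values were made by the authors for 35245 genes in 8 columns, 1 per library, and 0 columns were left unused. The deposited name calls these values FPKM, but in each library 100% of the values were whole multiples of 1 step within a tolerance of 0.01, and no division by gene length was left in them. Each step equalled the CPM of 1 read at the library size after trimmed-mean normalization as edgeR computes it, within 0.00434% in 7 libraries and 0.0304% in SUM159 1% oxygen library b. The values are therefore normalised CPM, which compare a gene between libraries and not long with short genes, and the whole reads were recovered from them. The depth of each library, from 12246208 to 39354600 reads, was taken from the recovered reads.

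The tests were chosen before the data were examined, as were the 23 gene lists, the rule for named genes and the other settings to be tried, except those named below as added. That plan took the values for FPKM and used limma (3.58.1, in R 4.3.3) on log2 values with a pseudocount of 0.5, with edgeR and its own filter in place of limma if the table held counts. The table held normalised values, so limma was kept although whole reads could be recovered from them. edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads of the same genes were run beside it. The choice matters, since edgeR called 1243 genes in MDA-MB-231 where limma called 572, and 162 noncoding genes there where limma called 61. With edgeR's own filter, run later, the counts were 1272 and 169 of 18654 genes tested. Genes with a value of at least 0.5 in at least 2 of 8 libraries were tested, 17785 in all. One mean per group was fitted over all 8 libraries, with a variance trend, and p was adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Contrasts were 1% against 20% oxygen in each line, the difference between these responses, and SUM159 against MDA-MB-231 at 20% oxygen. Overlaps were tested by Fisher's exact test.

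Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists, with the estimated correlation as an alternative. That alternative also rests on the 4 residual degrees of freedom of the fit, so it can lose a list whose members are not correlated. In SUM159 the pH regulation and mitophagy list had an estimated correlation of -0.066, under the preset one. Its camera p before adjustment still rose from 4.06e-05 to 0.0122. Of 485 list genes 454 were matched. Gene types came from GENCODE release 29, which describes another genome build than hg19. They were matched by gene identifier for 32799 genes, while 2446 matched none. Symbols came first from a separate list of gene names, which held 32556 of these genes, and otherwise from release 29. Coordinates are hg19 as the deposited table gives them. Named genes were 14 fixed in advance, the largest changes past the threshold per comparison among genes with both 1% libraries on the same side of both 20% libraries, and up to 4 called and 2 not called members of each list. Not every gene that the rule names is reported here. Where a group had 1 to 3 reads, the ratio of normalised levels is given with a 95% counting interval, and where it had 0 a bound at 3 reads over the group.

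The columns carry the letters a and b where the labels number the replicates 1 and 2, so columns were assigned to groups and not to single replicates. A block for the letter stood in for the planned block for the replicate number. Alternatives were pseudocounts of 0.1 and 1, other filters, quantile and median-ratio scaling, other variance models, each line alone, each library left out in turn, and, added after the data were seen, the letter blocks, removal of GC content and length trends, reads thinned to equal depth outside the mitochondrial ribosomal RNAs, and a spread per line. The tests were tested on simulated data with 200 changed genes per comparison. At 2-fold, limma recovered 51 of 67 changed genes in MDA-MB-231 and 48 of 67 in SUM159, at 1.5-fold 5 and 11 of 67, and at 4-fold 66 of 66 in both. More were recovered at 2-fold by edgeR (62 and 55 of 67) and DESeq2 (58 and 52 of 67). Of 17424 unchanged genes limma called 0 and 15, edgeR 2 and 3 and DESeq2 5 and 4. The simulated reads had 1 common dispersion (spread of read counts, 0.0152) for both lines and no trends with GC content or length. Changes were placed only in genes well covered by reads at 20% oxygen. These rates therefore do not describe the real libraries, which had such trends and a wider spread in SUM159. Differential splicing and unannotated transcripts were not analysed here, since the table holds gene totals.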

Results

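RNA was sequenced from 2 human triple-negative breast cancer cell lines, MDA-MB-231 and SUM159, kept at 20% or 1% oxygen for 24 hours. Total RNA libraries were prepared, so that coding and noncoding transcripts were both captured, and the series title names the noncoding transcriptome induced by hypoxia as its subject. The 8 libraries formed 4 groups of 2, a line at an oxygen level. The labels do not say whether the 2 libraries of a group came from separate cultures, so each p measures the spread between libraries. The reads assigned to genes came to 35526834 and 28526917 in MDA-MB-231 at 1% oxygen and to 28371558 and 39354600 at 20%. In SUM159 they came to 20449771 and 16164974 at 1% oxygen and to 12246208 and 15995976 at 20%. The mitochondrial ribosomal RNAs took between 14.1% and 17.4% of the reads in MDA-MB-231 and between 40.6% and 44.0% in SUM159. Levels below are in normalised CPM (reads scaled by library size), not divided by gene length, given as mean ± SD with n = 2 libraries per group. Log2 fold changes are 1% minus 20% oxygen, given with the standard error of the limma fit, and intervals from read counts cover counting error only. That fit shares 1 spread per gene over both lines. Replicates differed more in SUM159 (median SD 0.240 against 0.131 in MDA-MB-231 at levels under 5), so its standard errors may be too small.

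In MDA-MB-231, 15 of 26 genes of glucose breakdown, 5 of 13 of pH control and mitophagy and 7 of 17 of collagen modification rose at 1% oxygen, and 4 of 29 genes of DNA replication and 7 of 24 of mitosis fell. With an estimated correlation the pH and DNA replication lists passed (adjusted p = 0.0368 and 0.0368) and the glycolysis, collagen and mitosis lists did not (adjusted p = 0.0659, 0.0603 and 0.0503). CA9 (ENSG00000107159.8, chromosome 9, 35673852 to 35681156), a cell-surface carbonic anhydrase that regulates pH, rose from 0.339 ± 0.0158 to 6.36 ± 0.143 (log2 fold change 3.03 ± 0.22, adjusted p = 3.29e-04). BNIP3 (ENSG00000176171.7, chromosome 10, 133781577 to 133795435), a mitophagy receptor, rose from 47.7 ± 0.415 to 241 ± 11.4 (log2 fold change 2.32 ± 0.10, adjusted p = 3.19e-05). HIF1A (ENSG00000100644.12, chromosome 14, 62162230 to 62214976), which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, fell from 346 ± 19.6 to 142 ± 9.18 (log2 fold change -1.28 ± 0.11, adjusted p = 5.69e-04). Of 17785 genes tested, 382 rose and 190 fell, 572 in all or 3.22%. Among them, 128 rose and 12 fell by 2-fold or more.

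The 10 largest rises by the rule for named genes were those of DNAH11, NDRG1, TMEM45A, PPFIA4, CA9, RORA, DEPP1, HIF1A-AS3, ANGPTL4 and BNIP3. The rule admits a gene as one of a line's largest changes only where both libraries at 1% oxygen lie on the same side of both at 20%, in either line. DNAH11, an axonemal dynein heavy chain, rose from 3.61 ± 0.278 to 47.4 ± 3.13, and NDRG1, a stress-response gene, rose from 51.0 ± 0.916 to 504 ± 51.4. TMEM45A (log2 fold change 3.06), PPFIA4 (3.03), the nuclear receptor gene RORA (2.65) and the autophagy regulator gene DEPP1 (2.54) rose as well. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 2.36 ± 0.28 on the log2 scale (adjusted p = 0.00388). Besides HIF1A, the largest falls were those of MTRNR2L2 (-1.26), the pseudogene TPM3P6 (-1.25), the xenobiotic-metabolising cytochrome gene CYP1A1 (-1.21) and H3-7 (-1.2). PTGES, a prostaglandin E synthase gene (-1.13), the interferon-induced OASL (-1.12), the homeobox gene LHX4 (-1.12), the mRNA export factor gene ALYREF (-1.08) and the cold-inducible RBM3 (-1.08) made up the rest. MTRNR2L2 resembles the mitochondrial gene MT-RNR2 in sequence and TPM3P6 resembles TPM3, so reads shared with those genes are not excluded. In a group of 4 further genes named whatever their values, PDK1 (1.39), EGLN3 (1.81), LDHA (1.24) and VEGFA (0.97) rose. ADM, which encodes the vasodilator adrenomedullin, did not pass (0.41, adjusted p = 0.239), nor did EPAS1, the gene of the hypoxia-inducible factor 2 alpha subunit (-0.18, adjusted p = 0.356).

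**Figure D1:**
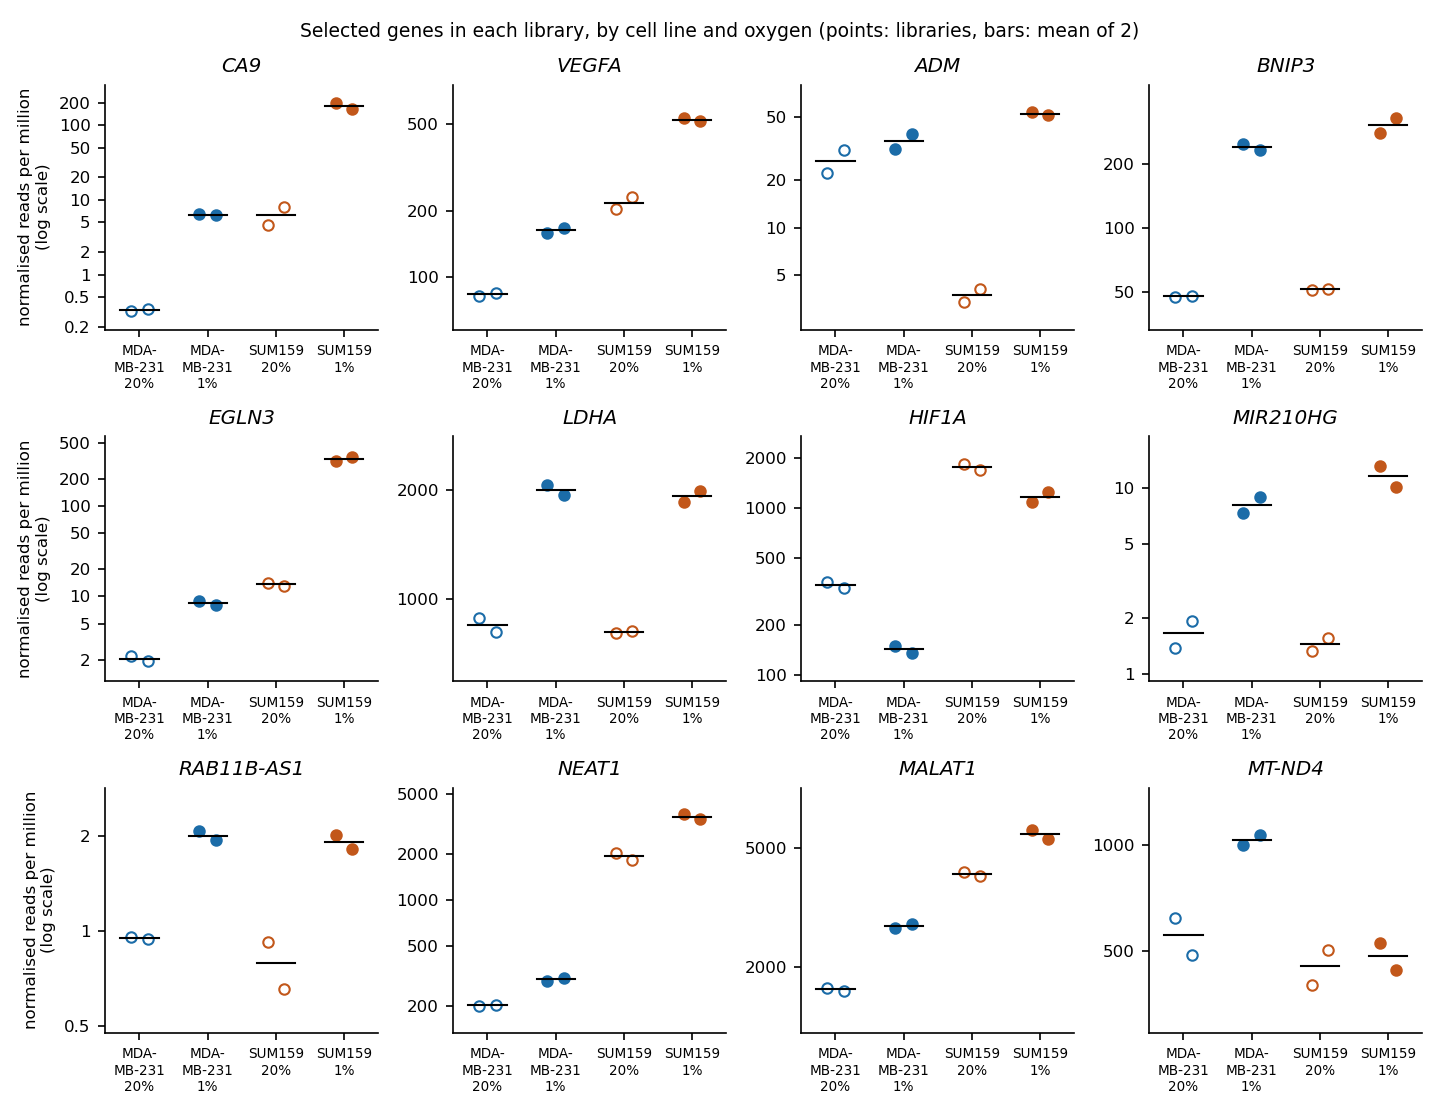
Normalised CPM (log axis) of 12 genes in each library; open points are libraries at 20% oxygen, filled points libraries at 1%, and bars the mean of 2. CA9 went from 0.339 to 6.36 in MDA-MB-231 and from 6.28 to 180.2 in SUM159, while HIF1A went from 346 to 142 and from 1756 to 1165. MALAT1 was higher at 1% oxygen in SUM159 on this scale, and its log2 fold change there turned to -0.31 with quantile normalization.

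Of 26 genes of glucose uptake and glycolysis, 15 rose in MDA-MB-231 and none fell (19 and 0 when adjusted over the list alone). Their median log2 fold change was 0.58 (camera adjusted p = 9.74e-19, adjusted p = 0.0659 with an estimated correlation), with PFKFB4 at 1.75, ENO2 at 1.48 and PGK1 at 1.38. GAPDH (0.34, adjusted p = 0.203) and ENO1 (0.39, adjusted p = 0.107) did not pass. In the oxygen sensing list, 6 of 15 rose, among them NDRG1, EGLN3, MXI1 and ANKRD37, and HIF1A fell (8 and 1 adjusted over the list alone; median 0.37, adjusted p = 8.96e-06, 0.0368 with an estimated correlation). In the list of angiogenic and secreted factors, 7 of 16 rose (8 adjusted over the list alone; median 0.48, adjusted p = 3.10e-08, 0.0368 with an estimated correlation). They included the calcium-regulating hormone gene STC1 (1.44) and IGFBP3 (1.26), whose product binds insulin-like growth factors. In the pH regulation and mitophagy list, 5 of 13 rose, with BNIP3L at 1.3 and DDIT4 at 1.14 (6 rose and 1 fell when adjusted over the list alone; median 0.29, adjusted p = 8.96e-06, 0.0368 with an estimated correlation). In the collagen modification list, 7 of 17 rose (8 adjusted over the list alone), with LOX, a collagen crosslinking enzyme, at 2.13 and the prolyl hydroxylase P4HA1 at 1.99. The collagen list's median was 0.27 (adjusted p = 5.79e-06, adjusted p = 0.0603 with an estimated correlation). Of 18 JmjC demethylase and TET genes, 5 rose (5 adjusted over the list alone), led by KDM3A (1.34) and KDM7A (1.16). Their median was 0.18 (adjusted p = 3.75e-04, adjusted p = 0.0503 with an estimated correlation).

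In the DNA replication list, 4 of 29 fell in MDA-MB-231 and none rose (20 and 0 adjusted over the list alone; median -0.41, adjusted p = 1.80e-13, 0.0368 with an estimated correlation). RRM1, a subunit of the enzyme that makes deoxyribonucleotides, fell by 0.63 on the log2 scale, the flap endonuclease gene FEN1 by 0.60 and the helicase gene MCM3 by 0.58. In the mitosis list, 7 of 24 fell (20 adjusted over the list alone), among them CDC20 (-0.69), BIRC5 (-0.66) and AURKB (-0.64). Its median was -0.43 (adjusted p = 1.20e-14, adjusted p = 0.0503 with an estimated correlation). In the list of homologous recombination and mismatch repair, EXO1 fell (-0.59), 1 of 19 (11 adjusted over the list alone; median -0.34). Its adjusted p was 3.75e-07, and adjusted p = 0.0777 with an estimated correlation.

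Of the 13 mRNAs encoded by the mitochondrial genome, 7 rose in MDA-MB-231 and none fell (11 and 0 adjusted over the list alone). Their median was 0.74 (adjusted p = 6.82e-10, adjusted p = 0.146 with an estimated correlation), from 1.25 for MT-ND3 and 0.90 for MT-ND4 to 0.11 for MT-ND1 and -0.31 for MT-ND6, which did not pass. In the ATF4 and unfolded protein response list, 3 of 20 rose (6 adjusted over the list alone), VLDLR (1.89), HERPUD1 (0.81) and DNAJB9 (0.74), with a median of 0.26 (adjusted p = 1.03e-05, 0.0425 with an estimated correlation). In the cholesterol synthesis list, 3 of 18 rose (7 adjusted over the list alone), among them HMGCS1 (0.76) and INSIG1 (0.69). The median was 0.24 (adjusted p = 3.19e-04, adjusted p = 0.0503 with an estimated correlation). In the interferon list, IFIT1 (-1.0), IFIT2 (-0.78) and IFIT3 (-0.61) fell, 3 of 23 (4 adjusted over the list alone; median -0.17, adjusted p = 0.00392). With an estimated correlation the interferon list had an adjusted p = 0.147. Of 37 replication-dependent histone genes 14 were matched to the table and all of these were tested, so the others were not assessed. H1-2 fell (-0.67), 1 of 14, and 2 fell when adjusted over the list alone. The histone list had a median of -0.33 (camera adjusted p = 0.00284, adjusted p = 0.285 with an estimated correlation). Among 20 host genes of small nucleolar RNAs, SNHG16 fell (-0.39; 1 adjusted over the list alone; median -0.13, adjusted p = 0.0127). That list had an adjusted p = 0.285 with an estimated correlation, and 0.0779 without 20% oxygen library b.

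The lists of nuclear-encoded oxidative phosphorylation (median -0.12, adjusted p = 0.101), cytosolic ribosomal proteins (-0.06, 0.194) and immediate-early and stress genes (0.12, 0.724) were not called in MDA-MB-231. Nor were the marker lists, epithelial and luminal (-0.11, 0.591), mesenchymal and basal (0.05, 0.0563), leukocyte (0.03, 0.921) and fibroblast (-0.05, 0.302). Adjusted over each list alone, members rose and fell in numbers of 2 and 4 for oxidative phosphorylation and 0 and 0 for ribosomal proteins and immediate-early genes. In the marker lists 1 epithelial and 3 mesenchymal members rose by that adjustment and none fell. The mesenchymal list was called without GC content and length trends (adjusted p = 0.0171), with reads thinned to equal depth (0.00934), with no filter (0.0380) and without 1% library a (0.0141) or 20% library a (0.0307). Oxidative phosphorylation was called without those trends (0.0224), with the column letter block crossed in SUM159 (0.0451), with no filter (0.0242) and without 20% library b (0.0372). For oxidative phosphorylation ATP5F1A fell and for mesenchymal markers CD44 rose when adjusted over all genes. The test of the leukocyte list pointed down where its median was positive, and the mean of the immediate-early list was -0.05 where its median was positive.

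The number of genes called in MDA-MB-231 moved with the settings. Leaving out 1 of its libraries leaves a group of 1, so that the spread then comes from the other groups. Without 1% oxygen library a, 1% library b, 20% library a or 20% library b of MDA-MB-231 the count was 85, 79, 105 or 82, and without SUM159 1% library a or b it was 332 or 328. It was 5 with each line fitted alone, 83 with a block for the column letter, 1243 with edgeR (812 rose, 431 fell), 1321 with DESeq2 (696 and 625), 2548 with GC content and length trends removed (1055 and 1493) and 2467 with the spread estimated per line (1298 and 1169). Of 82 named genes called in MDA-MB-231, 34 kept the call without each library in turn, CA9, NDRG1, BNIP3, HIF1A, DNAH11, LDHA and VEGFA among them. ANGPTL4 lost it without 1% oxygen library b, and MALAT1, NEAT1, IFIT3 and MT-ND4 each lost it without any of the 4 MDA-MB-231 libraries.

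In SUM159, 24 of 26 glycolysis genes, 10 of 15 of oxygen sensing and 11 of 16 of secreted factors rose at 1% oxygen, and 21 of 29 genes of DNA replication and 15 of 19 of DNA repair fell. None of these lists passed with an estimated correlation (adjusted p = 0.0852, 0.0562, 0.0562, 0.0562 and 0.0852). ANGPTL4 (ENSG00000167772.7, chromosome 19, 8428172 to 8439257) went from 2 reads in the 20% oxygen libraries to 2248 at 1%, a ratio of normalised levels of 1053 (95% interval 291 to 8702). NDRG1 (ENSG00000104419.10, chromosome 8, 134249413 to 134314265) rose from 46.0 ± 4.62 to 1959 ± 107 (log2 fold change 5.40 ± 0.11, adjusted p = 8.14e-08). CA9 rose from 6.28 ± 2.35 to 180.2 ± 22.4 (4.77 ± 0.22, adjusted p = 4.45e-06). EGLN3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, rose from 13.7 ± 0.69 to 335 ± 27.5 (4.56 ± 0.12, adjusted p = 4.79e-07). Of the 17785 genes, 3148 rose and 3386 fell, 6534 in all or 36.7%, and 973 and 842 did so by 2-fold or more.

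The other largest rises were those of HILPDA, a lipid droplet protein gene (4.60), PPFIA4 (4.41), HILPDA-AS1 (4.15), APLN, ARFGEF3 and the connexin gene GJB2 (4.0). APLN, which encodes the peptide hormone apelin, had 1 read at 20% oxygen and 218 at 1%, a ratio of 204 (95% interval 36.3 to 8104). ARFGEF3 had 1 and 196 reads, a ratio of 184 (32.6 to 7290.1). Among the largest falls were those of PPARGC1B, a coactivator of mitochondrial biogenesis (-2.72 ± 0.20, adjusted p = 3.09e-05), and CDC25A, a phosphatase that activates cell cycle kinases (-2.56 ± 0.15, adjusted p = 1.34e-05). The chloride channel gene PACC1 (-2.53), the anion channel subunit gene LRRC8B (-2.37), CCNJ (-2.33) and PAQR3 (-2.30) fell. So did PNPT1, a mitochondrial exoribonuclease gene (-2.32), UTP15, of ribosomal RNA processing (-2.23), and TSEN15 (-2.26), of the endonuclease that splices transfer RNA. Of the genes named whatever their values, ADM (3.64), BNIP3 (2.56), PDK1 (2.06), VEGFA (1.26) and LDHA (1.24) rose and HIF1A fell (-0.59, adjusted p = 0.00292). EPAS1 did not pass (0.21, adjusted p = 0.138).

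Of the 26 glycolysis genes, 24 rose in SUM159 and 1 fell (24 and 1 adjusted over the list alone; median 1.42, adjusted p = 7.61e-16, adjusted p = 0.0852 with an estimated correlation). PFKFB4 reached 3.36, ENO2 3.23, ALDOC 2.68 and the glucose transporter SLC2A1 2.15, while the lactate transporter SLC16A3 did not pass (0.21, adjusted p = 0.685). In the oxygen sensing list 10 of 15 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.98, adjusted p = 3.07e-05, adjusted p = 0.0562 with an estimated correlation). Among angiogenic and secreted factors 11 of 16 rose and 2 fell (11 and 2 adjusted over the list alone; median 1.25, adjusted p = 2.40e-05, adjusted p = 0.0562 with an estimated correlation). PGF, the placental growth factor gene, rose by 3.21 and IGFBP3 by 2.38, whereas FGF2 did not pass (-0.06, adjusted p = 0.816). In the pH and mitophagy list 8 of 13 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.95, adjusted p = 9.33e-05, adjusted p = 0.0562 with an estimated correlation). In the collagen list 12 of 17 rose and none fell (12 and 1 adjusted over the list alone), with LOX at 3.98, ERO1A at 1.74 and COL5A1 at 1.72. Its median was 1.02 (adjusted p = 2.36e-06, adjusted p = 0.0836 with an estimated correlation). Of the JmjC and TET genes 12 of 18 rose and 1 fell (13 and 1 adjusted over the list alone), among them KDM3A (1.24) and TET2 (1.17). Their median was 0.51 (adjusted p = 8.60e-05, adjusted p = 0.0562 with an estimated correlation).

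In the DNA replication list 21 of 29 genes fell in SUM159 and none rose (22 and 0 adjusted over the list alone; median -0.83, adjusted p = 1.26e-09, adjusted p = 0.0562 with an estimated correlation). MCM10 fell by 2.23 on the log2 scale, the sliding clamp gene PCNA by 1.81 and the helicase gene MCM6 by 1.41. In the repair list 15 of 19 fell (15 adjusted over the list alone), with XRCC3 at -1.57 and EXO1 at -1.19 (median -0.66, adjusted p = 3.16e-07, adjusted p = 0.0852 with an estimated correlation). The mitosis list was not called (median -0.09, adjusted p = 0.626), with 2 members up and 3 down of 24 (1 and 3 adjusted over the list alone). CCNA2 (-0.52) and CENPA (-0.52) fell and BIRC5 rose (0.45). In the list of nuclear-encoded oxidative phosphorylation 13 of 30 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.28, adjusted p = 0.00954, adjusted p = 0.560 with an estimated correlation). Cytochrome c, encoded by CYCS, fell at the mRNA level by 2.11, and NDUFA4L2, an inhibitor of respiratory complex I, went from 0 reads at 20% oxygen to 61 reads at 1%, at least 19.1-fold higher at 3 reads over the group. Without SUM159 20% oxygen library b the oxidative phosphorylation list had a median of -0.08 and was not called (adjusted p = 0.223).

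Of 18 cholesterol synthesis genes 8 fell in SUM159 and none rose (10 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.00243, adjusted p = 0.0852 with an estimated correlation), with IDI1 at -1.38 and FDFT1 at -1.15. Of 23 interferon genes 14 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.60, adjusted p = 2.40e-05, adjusted p = 0.0852 with an estimated correlation). IFIT1 (1.31), IFIT2 (1.26), IFIT3 (1.2) and the transcription factor IRF9 (1.14) were among those that rose. Among mesenchymal and basal markers 13 of 19 rose and 1 fell (14 and 1 adjusted over the list alone), with KRT17 at 2.07, S100A4 at 1.03 and VIM at 0.93, whose call ended with quantile normalization. The list's median was 0.54 (adjusted p = 9.08e-05, adjusted p = 0.128 with an estimated correlation), and both lines express such markers themselves. Of 35 cytosolic ribosomal protein genes 5 rose and none fell (1 and 0 adjusted over the list alone; median 0.26, adjusted p = 0.00107, adjusted p = 0.560 with an estimated correlation). That call ended with quantile normalization, where the median was -0.02 (adjusted p = 0.938) and RPLP0 turned from 0.41 to -0.02 and RPL4 from 0.03 to -0.40. It also ended without SUM159 20% oxygen library a (median 0.12, adjusted p = 0.114).

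Lists not called in SUM159 included the mitochondrially encoded mRNAs (median -0.17, adjusted p = 0.220; 2 of 13 fell, 1 adjusted over the list alone), which were called without SUM159 20% library a (-0.28, adjusted p = 0.0486) and with no filter (0.0495). The ATF4 and unfolded protein response list was not called (0.11, 0.645), with 6 members up and 4 down (7 and 4 adjusted over the list alone). VLDLR rose (2.57), and PSAT1 (-1.61) and ASNS (-1.48), enzymes of amino acid synthesis, fell. Replication-dependent histones (-0.35, 0.0524; 2 of 14 fell, 1 adjusted over the list alone) and small nucleolar RNA hosts (0.07, 0.621; 4 rose and 3 fell, 4 and 3 adjusted over the list alone) were not called. The histone list was called with the column letter block (0.0225, and 0.0142 with letters crossed in SUM159), the line alone (0.0230), median-ratio scaling (0.0462), no filter (0.00507), equal depth (0.0360) and without GC content and length trends (0.00798). It was also called without each MDA-MB-231 library (0.0310, 0.0309, 0.0370 and 0.0368 without 1% a, 1% b, 20% a and 20% b) and without SUM159 20% library a (-0.61, adjusted p = 0.00158). Epithelial markers (0.08, 0.482) had 3 members up and 1 down (2 and 1 adjusted over the list alone), and leukocyte markers (0.17, 0.516) 2 up of 6 (2 adjusted over the list alone). Among fibroblast markers (-0.01, 0.571) 2 of 9 rose (2 adjusted over the list alone), FAP (1.76) and COL1A1 (1.16), and the test pointed up where the median was negative. Immediate-early and stress genes (0.14, 0.892) had 5 up and 5 down of 15 (5 and 5 adjusted over the list alone), with FOS at 1.48, HSPA1A at -1.68 and HMOX1 at -1.23, and the test pointed down where the median was positive. The SUM159 count was 2984 with the line fitted alone and stayed within 1.5 times of 6534 under the other alternatives. With the spread estimated per line it was 4831 (2250 rose, 2581 fell), all of them among the 6534. Of 158 named genes called in SUM159, 129 kept the call without each library in turn.

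**Figure D2:**
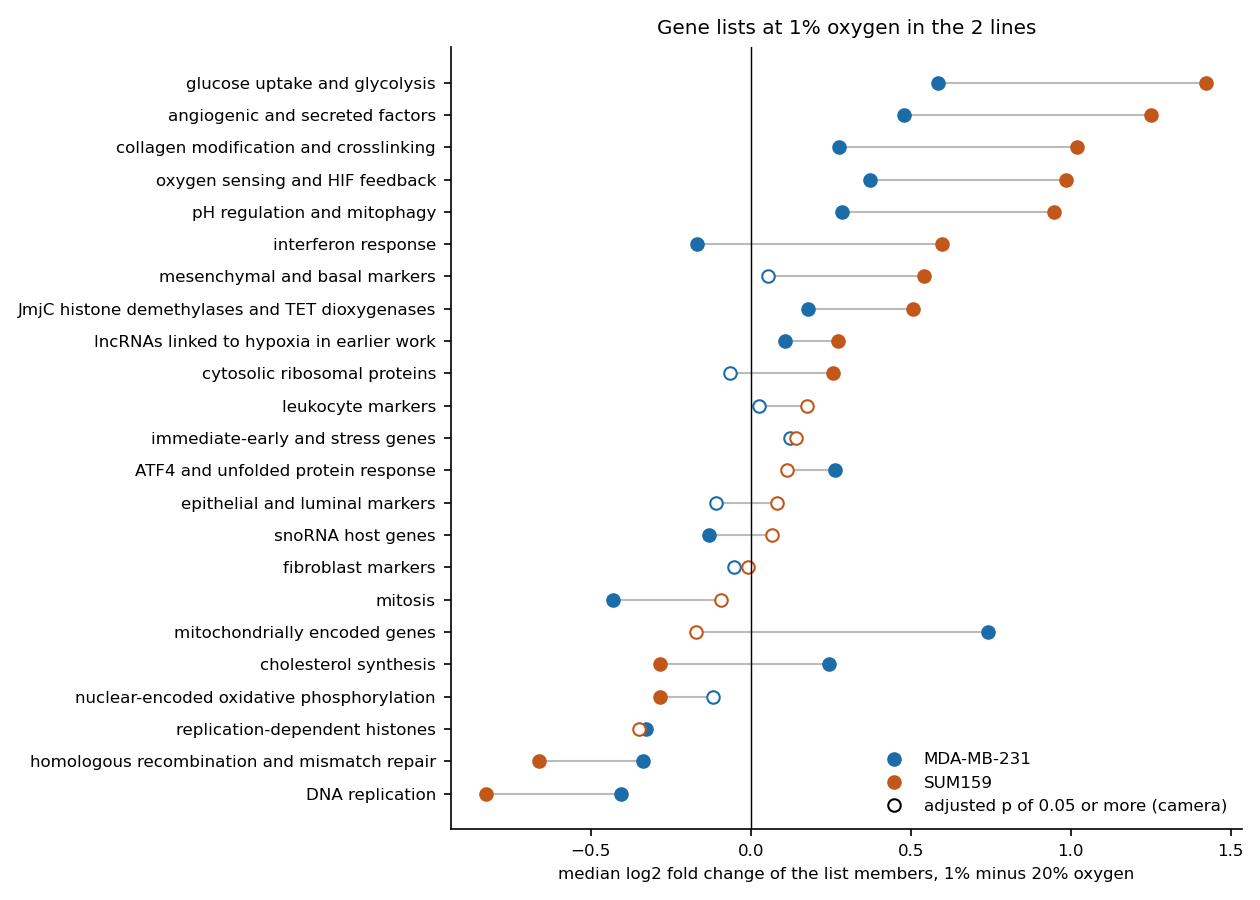
Median log2 fold change (1% minus 20% oxygen) of the members of 23 gene lists in each line; filled points had a camera adjusted p under 0.05 with the preset correlation and open points did not. Glycolysis stood at 0.58 in MDA-MB-231 and 1.42 in SUM159, and DNA replication at -0.41 and -0.83; the ribosomal protein median in SUM159 turned to -0.02 with quantile normalization.

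Most noncoding genes that changed at 1% oxygen rose. In MDA-MB-231, 56 noncoding genes rose and 5 fell, and in SUM159 529 rose and 180 fell. MIR210HG (ENSG00000247095.2, chromosome 11, 565659 to 568457), the host transcript of a hypoxia-induced microRNA, rose from 1.66 ± 0.393 to 8.13 ± 1.09 in MDA-MB-231 (2.00 ± 0.21, adjusted p = 0.00201) and from 1.45 ± 0.157 to 11.6 ± 2.10 in SUM159 (2.63 ± 0.21, adjusted p = 4.27e-05). NEAT1, the scaffold RNA of nuclear paraspeckles, rose in MDA-MB-231 (0.57 ± 0.10, adjusted p = 0.0215) and SUM159 (0.87 ± 0.10, adjusted p = 2.52e-04). RAB11B-AS1 (ENSG00000269386.1, chromosome 19, 8439256 to 8455569) rose in SUM159 from 0.790 ± 0.190 to 1.91 ± 0.142 (0.91 ± 0.18, adjusted p = 0.00399) and did not pass in MDA-MB-231 (0.951 ± 0.00914 and 2.00 ± 0.0907, 0.78 ± 0.18, adjusted p = 0.0513).

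The nuclear RNA MALAT1 rose in MDA-MB-231 (0.70 ± 0.11, adjusted p = 0.0163) and, at the deposited scaling, in SUM159 (0.44 ± 0.11, adjusted p = 0.0153), where quantile normalization turned it to -0.31. The largest noncoding rises in MDA-MB-231 were those of HIF1A-AS3, PDK1-AS1 (2.08), MIR210HG, LUCAT1 (1.79) and ADAMTS9-AS2 (1.72). HIF1A-AS3 (ENSG00000258667.1, chromosome 14, 62182275 to 62217815), transcribed from the strand opposite HIF1A, rose from 3.10 ± 0.323 to 19 ± 2.01 (2.44 ± 0.17, adjusted p = 2.62e-04) and had 0 reads in the 4 SUM159 libraries. The noncoding falls that met the rule were those of H3-7 (-1.2), ENSG00000266709 (-0.97), ENSG00000258964 (-0.79) and SNHG16 (-0.39). H3-7 was classed as noncoding by the gene type matched to its identifier, and it overlaps the protein-coding HIST2H3PS2 on its own strand. Whether H3-7 is a noncoding gene of its own is therefore uncertain. ENSG00000266709 overlaps HS3ST3B1 on its own strand, and ENSG00000258964 overlaps HIF1A and SNAPC1 on theirs. In SUM159 the largest rises were those of HILPDA-AS1, NR2F2-AS1, LINC00887 (3.12), SAP30-DT (3.07) and DIRC3 (2.98). NR2F2-AS1 had 3 reads at 20% oxygen and 196 at 1%, a ratio of 61.2 (95% interval 20.6 to 299). HILPDA-AS1 (ENSG00000240758.2, chromosome 7, 128095990 to 128109251) rose from 1.78 ± 0.670 to 39.2 ± 0.928 (4.15 ± 0.21) and overlaps HILPDA on its own strand. The largest falls in SUM159 were those of ENSG00000243960 (-2.08), which overlaps WDR77, the microRNA cluster host MIR17HG (-1.60), the small nucleolar RNA SNORD14D (-1.53), which lies within HSPA8, ENSG00000260196 (-1.52) and ENSG00000272077 (-1.52).

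By class, 51 long noncoding genes rose and 4 fell in MDA-MB-231, of 2251 tested, and 478 rose and 143 fell in SUM159. Among the 842 lincRNA genes 21 rose and 1 fell in MDA-MB-231 and 218 rose and 45 fell in SUM159, and among 783 antisense genes 17 and 0, and 144 and 47. Of 477 small or structural noncoding genes 5 rose and 1 fell in MDA-MB-231 and 51 rose and 37 fell in SUM159, and of 210 small nucleolar RNAs 20 rose and 25 fell in SUM159. The share of rises was larger among called long noncoding genes than among called protein-coding genes, 92.7% against 63.0% in MDA-MB-231 (odds ratio 7.47, Fisher's exact p = 1.77e-06) and 77.0% against 43.7% in SUM159 (odds ratio 4.30, p = 1.35e-57). That test looked for a difference in either direction, was chosen after the counts were seen, and treats genes as independent, which they are not. Called pseudogenes mostly rose too, 7 up and 2 down in MDA-MB-231 and 158 and 64 in SUM159. Genes without a matched type had 11 up and 2 down, and 98 and 98. The classes were not matched for level, so the larger share is not shown to be particular to long noncoding genes. In the list of long noncoding RNAs linked to hypoxia in earlier work 5 of 19 rose in MDA-MB-231 (8 adjusted over the list alone; median 0.11, adjusted p = 7.48e-06, 0.0368 with an estimated correlation). In SUM159 8 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.00606, adjusted p = 0.0852 with an estimated correlation), and with quantile normalization the list was not called (median 0.10, adjusted p = 0.0647). UCA1 rose in SUM159 by 1.98 and LUCAT1 by 2.12, while NORAD (0.05 and 0.10) and TUG1 (0.14 and -0.06) did not pass in either line. H19 had 0 reads at 20% oxygen in SUM159 and 22 at 1%, at least 6.87-fold higher at 3 reads over the group. The noncoding count in MDA-MB-231 was 162 with edgeR, 92 with DESeq2 and 287 with the spread estimated per line, 8, 7, 11 and 8 without 1% library a, 1% library b, 20% library a and 20% library b, and 93 without SUM159 20% library b. In SUM159 it was 439 with edgeR (330 rose, 109 fell), 271 with DESeq2 (207 and 64) and 486 with the spread estimated per line (371 and 115). Quantile normalization gave 414 rises and 254 falls there. Which strand was counted is not given in the sources used here, and 102 of the 224 named genes overlap a gene on the opposite strand.

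The lines shared part of their response. Of the genes raised in MDA-MB-231, 251 were also raised in SUM159, where 67.6 would be expected of independent lists (odds ratio 9.59, Fisher's exact p = 3.95e-98), and 100 were lowered in both (36.2 expected, odds ratio 4.84, p = 2.13e-25). CA9, NDRG1, BNIP3, EGLN3, LDHA and MIR210HG were raised in both, and HIF1A was lowered in both. Among long noncoding genes 35 were raised in both (10.8 expected, odds ratio 8.66, Fisher's exact p = 2.29e-13). The genes raised in both had a median log2 fold change of 0.84 in MDA-MB-231 and 1.24 in SUM159. Called changes were opposite for 19 genes raised in MDA-MB-231 and lowered in SUM159 (72.7 expected) and for 23 lowered and raised (33.6 expected). Genes are not independent replicates, and across them the 2 sets of log2 fold changes correlated at r = 0.31. Both sets of calls also used the same spread per gene, which the expected counts and Fisher's exact p ignore. The count of 351 shared changes was 619 with edgeR and 642 with DESeq2, 71, 66, 80 and 68 without 1% library a, 1% library b, 20% library a and 20% library b of MDA-MB-231, and 202 and 194 without SUM159 1% library a and b.

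The response itself differed between the lines for 3209 genes, 1453 with a higher log2 fold change in SUM159 and 1756 with a lower one. ANGPTL4 (difference 5.01, adjusted p = 4.24e-04), HILPDA (3.90) and PGF (3.46) responded more in SUM159. So did NRN1, a neuronal growth protein gene (3.97), ZP1, a gene of an egg-coat glycoprotein (3.85), and HILPDA-AS1 (3.66). ZP1 had 1 read in SUM159 at 20% oxygen and 183 at 1%, a ratio of 171 (95% interval 30.4 to 6809), and NRN1 had 3 reads over the 4 MDA-MB-231 libraries, so its value only repeats the rise in SUM159. The NRN1 difference was larger with edgeR and not called (4.72, adjusted p = 0.0840), as was that of ZP1 with edgeR (5.28, adjusted p = 0.191) and DESeq2 (5.06, adjusted p = 0.0765). CXCL8, a neutrophil chemokine gene, rose in MDA-MB-231 from 7.04 ± 1.02 to 14.2 ± 2.17 and fell in SUM159 from 655 ± 59.6 to 179 ± 42.9 (difference -2.84, adjusted p = 6.62e-04). HIF1A-AS3 (-2.44), PPARGC1B (-2.35), CCNJ (-2.33), TSEN15 (-2.30) and DNAH11 (-2.29) had the other largest negative differences. For HIF1A-AS3, with 0 reads in the 4 SUM159 libraries, that value only repeats the rise in MDA-MB-231, and it was not called with edgeR (-2.65) or DESeq2 (-2.70). Among genes named whatever their values, CA9 (1.74), ADM (3.23), PDK1 (0.67) and EGLN3 (2.75) rose more in SUM159 and HIF1A fell less there (0.69). The CA9 difference moved with the pseudocount and was not called at 0.1 (0.99, adjusted p = 0.0869), with edgeR (0.59, adjusted p = 0.331) or with DESeq2 (0.62, adjusted p = 0.246). For VEGFA (0.29, adjusted p = 0.148), BNIP3 (0.24, adjusted p = 0.266) and RAB11B-AS1 (0.13, adjusted p = 0.756) no difference was called. LDHA (0.00) and NEAT1 (0.30) had none at the deposited scaling, and with quantile normalization both were called lower in SUM159 (-0.66, adjusted p = 0.00810, and -0.40, adjusted p = 0.0424).

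Of the 6141 genes called in SUM159 and not in MDA-MB-231, 2735 had a called difference, as did 108 of the 179 called in MDA-MB-231 alone. Of 23 lists, 13 differed in response by the preset correlation, and none with an estimated one. The estimated one also leaves fewer degrees of freedom, so this loss does not show that list members were correlated. The median differences were 0.91 for glycolysis, 0.58 for angiogenic factors, 0.38 for oxygen sensing, -0.39 for DNA replication and 0.37 for mitosis, of whose 24 members 7 had a called positive difference (7 adjusted over the list alone). For those lists the adjusted p = 0.253, 0.153, 0.126, 0.183 and 0.253 with an estimated correlation. The mitochondrially encoded mRNAs (-0.90, 10 of 13 with a called negative difference), cholesterol synthesis (-0.70, 11 of 18) and the interferon genes (0.74, 8 of 23 positive and 1 negative) also differed. Cholesterol synthesis and interferon genes were called in opposite directions in the 2 lines, and the mitochondrial mRNAs were called in MDA-MB-231 and not in SUM159. None of these calls passed otherwise (in MDA-MB-231 adjusted p = 0.0503, 0.147 and 0.146, in SUM159 0.0852 and 0.0852, with an estimated correlation). Adjusted over each list alone these counts were 11, 12 negative and 1 positive, and 15 positive and 1 negative, and with an estimated correlation adjusted p = 0.273, 0.126 and 0.126. The count of 3209 fell to 1028, 1635, 1182 and 1747 without MDA-MB-231 1% library a, 1% library b, 20% library b and 20% library a, and to 1972 without SUM159 1% library a. It was 1653 with a block for the column letter, 2046 with no filter on low values and 5006 with GC content and length trends removed, and the PDK1 and HIF1A differences lost their calls in several of these.

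**Figure D3:**
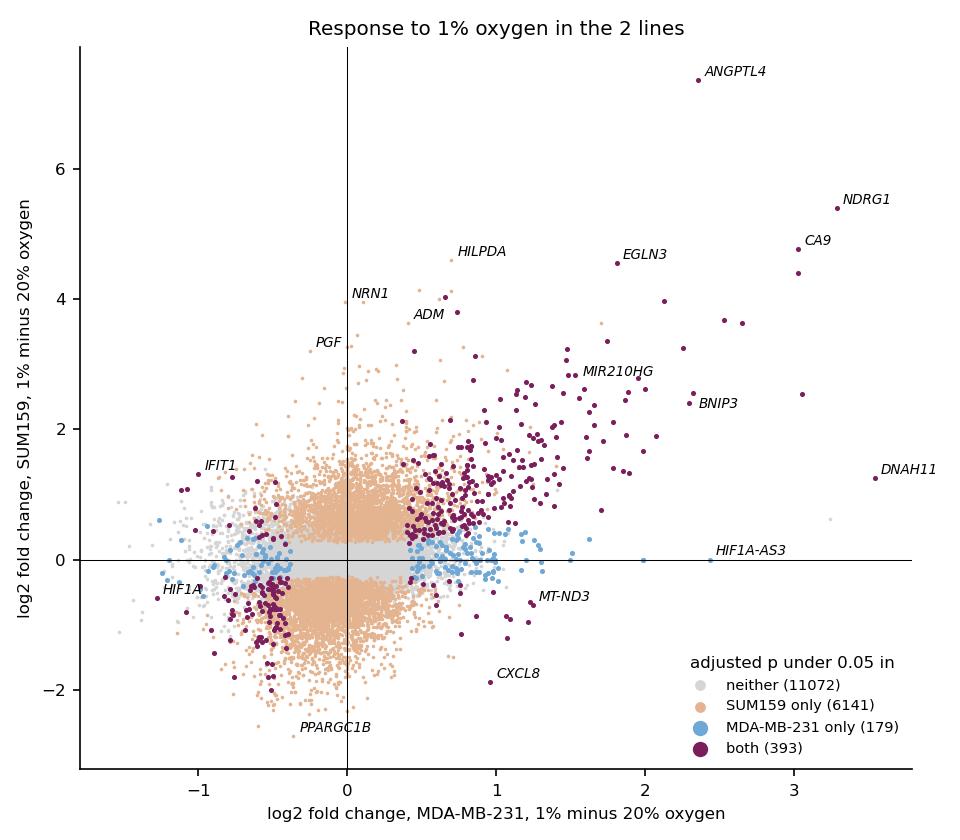
Log2 fold change (1% minus 20% oxygen) of each of 17785 genes in MDA-MB-231 (horizontal) and SUM159 (vertical), coloured by where the adjusted p was under 0.05. The 393 genes called in both lines lie mostly along the diagonal from lower left to upper right, and 6141 genes were called in SUM159 only and 179 in MDA-MB-231 only.

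At 20% oxygen the lines differed in 12098 genes, 5264 higher and 6834 lower in SUM159, given as context for the difference in response. HIF1A (1756 ± 97.2 against 346 ± 19.6), NEAT1 (1937 ± 137 against 202 ± 1.91) and CXCL8 (655 ± 59.6 against 7.04 ± 1.02) were higher in SUM159. The largest differences towards SUM159 that are given here were those of the receptor tyrosine kinase gene ROS1 (341 ± 27.1), the cytokine gene IL33 (279 ± 15.9), ENSG00000198518 (276 ± 39.4), which matched no symbol, and the aldo-keto reductase gene AKR1C2 (297 ± 12.4). ROS1 had 3 reads in MDA-MB-231 at 20% oxygen, a ratio of 10928 (95% interval 3738 to 53004), and IL33 had 0, at least 8982-fold higher in SUM159 at 3 reads over the group. XIST was also named by the rule, and its levels are not given. Higher in MDA-MB-231 were the peroxidase gene PXDN (271 ± 12.2), ANKRD1 (229.9 ± 9.35), the glycogen phosphorylase gene PYGL (136 ± 6.0) and the extracellular matrix gene FRAS1 (99.8 ± 8.38). FRAS1 had 0 reads in SUM159 at 20% oxygen, at least 722-fold lower at 3 reads over the group, and PXDN had 2, a ratio of 2988 (95% interval 827 to 24678). ANKRD1 had 2 reads there and PYGL 1, ratios of 2509.6 (695 to 20724) and 2977 (534 to 117599). The median log2 difference over all genes was -0.14 and was not subtracted, so these differences and the split by direction include that shift. The split was more even with edgeR (5846 higher and 6058 lower), DESeq2 (5432 and 5435) and reads thinned to equal depth (5522 and 5617).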

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

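The differences between the lines below come from planned tests, and the tests of technical explanations were chosen after the results were seen. The test of the difference in response picked out 3209 genes. It picked out 13 of the 23 lists, with median differences in log2 fold change of 0.91 for glycolysis, 0.38 for oxygen sensing, 0.58 for angiogenic factors, 0.47 for pH regulation and mitophagy, 0.61 for collagen modification, -0.39 for DNA replication, 0.37 for mitosis, -0.37 for homologous recombination and mismatch repair, -0.90 for mitochondrially encoded mRNAs, -0.70 for cholesterol synthesis, 0.74 for interferon genes, 0.31 for ribosomal proteins and 0.49 for mesenchymal markers. With an estimated correlation 0 of the 23 lists passed. Quantile normalization ended the calls of the pH (adjusted p = 0.0822), collagen (0.176), ribosomal (0.518) and mesenchymal (0.0610) lists.

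Of 224 named genes, 128 differed in response by that test, and the 17 fixed in advance or largest are given. They were CA9 (1.74), ANGPTL4 (5.01), ADM (3.23), PDK1 (0.67), EGLN3 (2.75), HIF1A (0.69), NRN1 (3.97), HILPDA (3.90), ZP1 (3.85), HILPDA-AS1 (3.66), PGF (3.46), CXCL8 (-2.84), HIF1A-AS3 (-2.44), PPARGC1B (-2.35), CCNJ (-2.33), TSEN15 (-2.30) and DNAH11 (-2.29). The calls of CA9, HIF1A-AS3 and ZP1 ended with edgeR and with DESeq2, that of NRN1 with edgeR, and that of CA9 also with a pseudocount of 0.1. HIF1A-AS3 had 0 reads in SUM159 and NRN1 3 in MDA-MB-231, so these values only repeat the rise in the other line. HIF1A lost its call without any MDA-MB-231 library or SUM159 1% library b, and PDK1 lost it without each library in turn but SUM159 20% library a.

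More genes changed in SUM159 (6534) than in MDA-MB-231 (572). SUM159 was the shallower line, and outside mitochondrial ribosomal and small RNA the lowest MDA-MB-231 library had 2.18 times the reads of the highest SUM159 library. That order does not decide on unequal depth, since the lines share 1 spread per gene and few reads widen the spread in SUM159. With reads thinned to equal depth outside the mitochondrial ribosomal RNAs, SUM159 had 5529 calls and MDA-MB-231 393. This argues against unequal depth as the whole cause. Trends with GC content and length could not be the whole cause, since the ratio of called genes was 3.25 without them. The noise-corrected SD of the log2 fold changes was 2.11 times larger in SUM159. Its noise was taken from libraries of the same group, and the labels do not say whether these were separate cultures. Noise between cultures may therefore remain in that SD, so it does not decide whether a spread shared by the lines was the whole cause. The shared spread and the trends may each be part of the cause. MDA-MB-231 had 2467 calls with a spread per line and 2548 with the trends removed, and both changes together left a ratio of 1.21. The number of called genes therefore says little about how much more SUM159 responded, whereas the SD stays open as a difference between the lines, as a hypothesis.

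In MDA-MB-231 the mitochondrially encoded mRNAs were higher at 1% oxygen with the preset correlation (7 of 13 rose), and the list did not pass with an estimated one (adjusted p = 0.146 with an estimated correlation). Trends with GC content and length were argued against by a median of 0.62 once they were removed, and a single library by a lowest median of 0.50 with each library left out. Of the 13 mRNAs, MT-ND1 and MT-ND6 lay 3 standard errors or more under the median, also with those trends removed. That limit was set after their values were seen, and both fits use the same libraries. It therefore does not decide whether all 13 mRNAs rose alike. The ribosomal RNAs MT-RNR1 (0.47 ± 0.20) and MT-RNR2 (0.12 ± 0.42) did not decide it either. A change in the processing or stability of some of these mRNAs may remain as a hypothesis, and it was not tested.

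With the preset correlation interferon genes were lower at 1% oxygen in MDA-MB-231 (3 of 23 fell) and higher in SUM159 (14 rose and 1 fell), and neither passed otherwise (adjusted p = 0.147 and 0.0852 with an estimated correlation). The median difference was 0.66 with GC content and length trends removed and at lowest 0.55 with each library left out, which argues against both as the cause. A difference between the lines in this pathway may remain as a hypothesis, and with an estimated correlation the list's difference did not pass (adjusted p = 0.126).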

How the results depend on the processing

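The letter blocks, GC content and length correction, equal depth and spread per line were chosen after results were seen, and the other alternatives were planned. Of 27 settings in all, the estimated correlation was run for lists only, and edgeR and DESeq2 for genes only. Over the settings run for genes, 15855 results of named genes kept their direction and side of the threshold, 562 gained a call, 1021 lost one and 7 reversed. For lists these numbers were 1608, 45, 46 and 0. The causes of these moves were not tested except where named. The 7 reversals were MALAT1 (-0.31), RPLP0 (-0.0166) and RPL4 (-0.40) in SUM159 and the differences in response of LDHA (-0.66), NEAT1 (-0.40) and PGK1 (-0.0379) with quantile normalization, and that of TPM3P6 (-2.98) with edgeR.

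The 572 genes changed in MDA-MB-231 became 203 with no filter, 879 with quantile normalization, 281 with no variance trend, 5 with each line fitted alone (which leaves 4 libraries to a fit), 1243 with edgeR, 1321 with DESeq2, 2548 without GC content and length trends, 2467 with a spread per line and 5332 with both. The 61 noncoding genes became 25 with no filter, 0 with the line alone (limma; edgeR on all 8 libraries 162, DESeq2 92), 147 without the trends, 40 at equal depth, 287 with a spread per line and 433 with both. In SUM159 the 6534 genes became 2984 with the line alone, and the 709 noncoding genes 265 so, 439 with edgeR and 271 with DESeq2. With a spread per line these SUM159 counts were 4831 and 486. The 351 genes changed alike in both lines became 140 with no filter, 189 with no variance trend, 5 with each line alone, 619 with edgeR, 642 with DESeq2, 1504 without the trends, 973 with a spread per line and 2290 with both. The 3209 differences in response became 2046 with no filter and 5006 without the trends. With an estimated correlation the called lists fell from 16 to 6 in MDA-MB-231, from 14 to 0 in SUM159 and from 13 to 0 for the difference. That alternative has fewer degrees of freedom, so the fall does not measure correlation between members alone.

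Libraries of the same letter deviated together in MDA-MB-231 (correlation 0.64) and apart in SUM159 (-0.59), and the letters are not the labels' replicate numbers. With a replicate block for the letter the counts were 83 for MDA-MB-231, 10 for its noncoding genes, 68 for both lines and 1653 for the difference. With the letters of the block crossed in SUM159 they were 2768, 178, 1369 and 5804, and with the trends removed as well 2994, 174, 1684 and 5613. The histone list in SUM159 was called with either block (adjusted p = 0.0225, and 0.0142 crossed). Between letters, library a minus b correlated with GC content at -0.70 and -0.56 in MDA-MB-231 and 0.53 and -0.62 in SUM159.

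With each library left out in turn, counts ranged from 79 to 743 for MDA-MB-231 (85, 79, 105 and 82 without its 1% library a, 1% b, 20% a and 20% b, 332 and 328 without SUM159 1% a and b) and from 7 to 93 for its noncoding genes (8, 7, 11 and 8 in that order, 93 without SUM159 20% b). They ranged from 4908 to 6309 for SUM159, 553 to 714 for its noncoding genes, 66 to 388 for both lines (71, 66, 80 and 68, then 202 and 194) and 10302 to 12204 at 20% oxygen. For the difference they ranged from 1028 to 3877 (1028, 1635, 1747 and 1182, and 1972 without SUM159 1% a). Called lists ranged from 16 to 17, 13 to 15 and 13 to 15. With reads outside the mitochondrial ribosomal RNAs thinned to equal depth MDA-MB-231 had 393 calls and SUM159 5529, and genes with few reads carry the wider replicate spread, a median SD of 0.131 in MDA-MB-231 and 0.240 in SUM159 under a level of 5 against 0.0814 and 0.118 over 50.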

Other observations

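The lists of ribosome biogenesis, chaperones and tRNA synthetases and the antisense pairs were chosen after results were seen, and the prediction for nucleotide synthesis was written before its values were examined. For the lists chosen so, p values come from data already seen, so they describe the lists and are not independent evidence. Adjustment was over these lists and nucleotide synthesis alone. Of 29 genes of ribosome biogenesis, 24 fell in SUM159 (median -1.23, adjusted p = 4.96e-13, 0.0354 with an estimated correlation) and 6 in MDA-MB-231 (-0.39, 7.55e-11), with NOP2 at -2.03 and NOLC1 at -2.01 in SUM159. Of 16 heat-shock chaperone genes 12 fell in SUM159 (median -1.12, adjusted p = 4.78e-09, adjusted p = 0.0757 with an estimated correlation) and 1 in MDA-MB-231 (-0.26, adjusted p = 0.00290, adjusted p = 0.295 with an estimated correlation), with HSPH1 at -2.22 and HSP90AA1 at -1.51. Of 20 cytosolic aminoacyl-tRNA synthetase genes 12 fell and 1 rose in SUM159 (median -0.49, adjusted p = 9.54e-06, adjusted p = 0.105 with an estimated correlation), with MARS1 at -1.88, and 1 rose in MDA-MB-231 (-0.05, 0.0603). The differences between the lines were -0.81, -0.97 and -0.32 (adjusted p = 4.92e-09, 3.70e-08 and 2.42e-04), and none passed otherwise (adjusted p = 0.0696, 0.113 and 0.181 with an estimated correlation).

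Over 660 pairs of an antisense gene and a protein-coding gene on the opposite strand, the log2 fold changes correlated at 0.17 in SUM159 (permutation p = 0.001, the smallest these permutations can give) and 0.03 in MDA-MB-231 (p = 0.353). Both members were called in 74 pairs in SUM159, 51 in the same direction, and in 2 in MDA-MB-231, 1 in the same direction. Which strand was counted is not given in the sources used here. Reads of the coding gene counted for its partner could give such a correlation and are not excluded, and shuffling the pairs does not test this.

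MYC, a transcription factor gene, fell in SUM159 (-0.87 ± 0.13, adjusted p = 9.05e-04) and did not pass in MDA-MB-231 (0.31, adjusted p = 0.218). Lower MYC may go with lower expression of its target genes, and as a hypothesis this predicted a fall of purine and pyrimidine synthesis genes. Their median in SUM159 was -0.70 (11 of 16 fell, adjusted p = 2.34e-05, adjusted p = 0.0757 with an estimated correlation), with CTPS1 at -2.22 and GART at -1.87. In MDA-MB-231, where MYC did not pass, 1 of 16 fell (median -0.32, adjusted p = 1.07e-05, adjusted p = 0.0923 with an estimated correlation), and the difference between the lines was -0.42 (adjusted p = 0.00987, adjusted p = 0.181 with an estimated correlation). Other causes stay open.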
